A study of Mus musculus with 16 samples.

How the data were processed

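RNA of 100 sorted NSCs per library was profiled by Smart-seq2 with Nextera XT libraries and Illumina NovaSeq sequencing, in 16 libraries of 4 groups with 4 biological replicates each. The deposited table held whole-number read counts for 25746 genes, not normalized, with 1 column per library. Per the submitters' processing notes, cutadapt 2.10, STAR 2.7.6a, featureCounts, Subread 1.6.3, Seurat 3.0 and R 4.0.3 were used; these notes name tools with no role or order. They name the builds GRCm38.p6 and mm9, and which one served for the counts is not given in the sources used here. How the counting treated strand and reads with several positions is not given either, so values of genes with overlapping partners or near-identical copies are uncertain. That applies to ribosomal protein genes, which have many pseudogene copies, as Gapdh and Hmgb1 do, and to named genes whose exons overlap another gene by more than 5% of their length, such as Banf1 (28.6%), Rps25 (24.8%), Rpl5 (24.3%), Spp1 (18.8%), Rad54l (15.4%), Rpl32 (14.5%), Psmb5 (12.1%), Psmb7 (11.8%), Aldh1l1 (11.1%), Rab26 (9.36%), Lbr (9.24%), Rpl4 (7.87%) and Notch2 (5.02%), and Hes5 (31.8%) and Cryab (17.0%) in the closing section. Positions, lengths and GC content came from GENCODE M21 on GRCm38, where 25635 of the 25746 identifiers matched. Gene symbols are those of the deposited table.

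Groups came from the sample labels. Replicate numbers follow the order of the samples, carry no pairing, and no batch is named in the labels. Each library counted as 1 replicate. No pair of libraries within a group agreed within sampling noise, with a smallest chi-square per degree of freedom of 28.1 over the 24 pairs. That argues against 1 library entered more than once. It cannot show whether libraries came from different animals, since amplification adds to the differences between libraries of the same cells. Whether the cells were transduced in the animal or in culture is not given in the sources used here, nor is the species of the Lamin B1 insert.

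Differences were tested with edgeR 4.0.16 in R 4.3.3 on the deposited counts. Genes were filtered with filterByExpr by group (minimum count 10, minimum total 15), which left 12710 genes; 8853 genes had 0 counts in all libraries. Library sizes were scaled with TMM. One model with a mean per group was fitted to all 16 libraries with estimateDisp and robust glmQLFit, so that the groups share 1 estimate of the spread. Contrasts were tested two-sided with glmQLFTest, edgeR's quasi-likelihood test, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Every adjusted p of a gene in the text is from this test unless another tool is named. Levels are CPM, counts scaled to a TMM-scaled library size of 1000000, given as mean ± SD over libraries; log2 fold changes are given ± SE. Lmnb1, Lmnb2 and Lmna were also compared by an exact two-sided permutation test of log2 CPM (prior count 2), which cannot go below 0.0286 with 4 against 4 libraries.

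Before the data were examined, 33 gene lists (25 of pathways, 8 of cell types), the designs, the alternatives and the rule for naming genes were fixed. For the 32 lists with a member tested, camera with a preset correlation of 0.01 was run on the counts and estimated dispersions of the same model. Benjamini-Hochberg adjustment was made over the lists. Camera with an estimated correlation and fry were alternatives; none of the lists called in the 2 comparisons of the report held with an estimated correlation. Counts of members are given over all genes tested and adjusted over the list alone. The age and LMNB1 fold changes were compared across genes by Pearson's r and Spearman's rho, with all 70 assignments of the LMNB1 and CFP libraries as the permutation, and the genes called with age were tested as lists in the LMNB1 comparison.

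The genes named were the 3 lamin genes; the 8 with the largest fold change per direction among called genes with a mean log2 CPM of at least 3 and no overlap between groups; where fewer than 4 met this, the 4 with the smallest p per direction; the 4 members with the smallest p of each called list; and, as an option, members of any list past the threshold and the 2 most abundant members of lists not called. The comparison of CFP with old libraries took 4 genes per direction. Genes chosen by smallest p per direction also had a mean log2 CPM of at least 3. Predicted or unnamed genes and pseudogenes were left out of both choices. Which optional members are printed, and how many of each called list, was settled after their values were seen, and some genes that the rule names are not reported here. Egr1, Fosb, Cspg4 and Slc1a2 in the comparison of CFP with old libraries lie outside the rule and were chosen after their values were seen.

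The statistical steps were tested on simulated counts of the 12710 genes with 100 genes changed at each fold. The changed genes were drawn from those with a mean log2 CPM of at least 3, so recovery of genes with lower levels was not tested. At 2-fold, 8% were recovered in the old against young and 9% in the LMNB1 against CFP simulation; at 4-fold, 66% and 60%, with 0 and 2 false calls. A list with raised members was called and 0 of 30 unchanged lists were. The simulated genes were drawn independently of each other. That result therefore does not cover false calls of lists whose members move together, such as ribosomal protein genes (estimated correlation 0.80 with age). Total counts ran from 9801725 to 21997179, and 100 cells per library limit the precision of genes with few molecules per cell. No molecular identifiers are given in the labels, so counts include amplification copies.

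Alternatives planned were DESeq2 size factors, library size only, no filter, a stricter filter (1 CPM and 10 counts in 8 libraries), DESeq2 1.42.0, limma 3.58.1 voom without and with sample quality weights, the 8 compared libraries alone, a fit without robust estimation, counts thinned to the smallest library, the number of detected genes as a covariate, and each library left out in turn. Chosen after seeing the data were offsets for transcript length, GC content and both (lowess trends per library, span 0.3), and the correlation without 4 lists. For 12698 of the 12710 genes a length was known. The comparison of CFP with old libraries is not named in the study's design and is given only as an additional observation.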

Results

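The series measured gene expression in neural stem cells (NSCs) of the mouse hippocampus, the cells that give rise to new neurons in the adult dentate gyrus. All mice were C57BL/6. Each library was made from 100 flow-sorted cells with Smart-seq2, a protocol for very small amounts of RNA in which poly(A) RNA is copied into full-length cDNA and amplified. The 16 libraries fell into 4 groups with 4 biological replicates each: NSCs of young mice aged 6 weeks, NSCs of old mice aged 9 months, old NSCs carrying a control retrovirus that encodes cyan fluorescent protein (CFP), and old NSCs carrying a retrovirus that adds Lamin B1 to the same reporter (LMNB1). Total counts per library ranged from 9801725 in CFP replicate 4 to 21997179 in old replicate 4. The number of genes detected was 11871 ± 409 in young, 13196 ± 401 in old, 12817 ± 184 in CFP and 13002 ± 336 in LMNB1 libraries (mean ± SD, n = 4 each). The design addressed 2 questions, which transcripts differ between young and old NSCs and which differ between old NSCs with the Lamin B1 virus and those with the control virus.

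Lmnb1 (ENSMUSG00000024590), which encodes the nuclear lamina protein Lamin B1, lies on chromosome 18 from 56707813 to 56753424 on the + strand of GRCm38. It was measured at 18.4, 16.9, 15.7 and 12.7 CPM in young replicates 1 to 4 and at 14.9, 7.27, 9.67 and 5.68 CPM in old replicates 1 to 4. The group means were 15.9 ± 2.42 CPM in young and 9.37 ± 4.02 CPM in old libraries (SD, n = 4 each). The log2 fold change of -0.76 ± 0.49 (SE) did not pass the test, with an adjusted p of 0.401, and the exact two-sided permutation test of the 4 against 4 values gave p = 0.0571 (0.129 after Benjamini-Hochberg adjustment over the 9 such tests of lamin genes). CFP replicates 1 to 4 held 7.94, 8.37, 4.91 and 8.96 CPM (7.54 ± 1.81), and LMNB1 replicates 1 to 4 held 9.95, 12.1, 33.8 and 46.2 CPM (25.5 ± 17.5). Every LMNB1 library lay above every CFP library, and the exact two-sided permutation test gave p = 0.0286 (0.129 adjusted), the smallest value that 4 against 4 libraries can give. The log2 fold change of LMNB1 over CFP was 1.76 ± 0.51, with an unadjusted p of 0.0022 and an adjusted p of 0.228 over all genes tested. The counts do not separate transcripts of the virus from those of the endogenous gene.

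The other lamin genes did not pass edgeR's test in either comparison. Lmnb2, which encodes Lamin B2, was at 16.0 ± 2.91 CPM in young and 8.54 ± 3.53 CPM in old libraries (log2 fold change -0.90 ± 0.50, adjusted p = 0.297), and at 7.12 ± 2.59 CPM in CFP and 9.76 ± 3.04 CPM in LMNB1 libraries (0.45 ± 0.49, adjusted p = 0.792). Lmna, the gene of the A-type lamins, was at 13.6 ± 4.90 CPM in young and 5.83 ± 1.87 CPM in old libraries (-1.22 ± 0.64, adjusted p = 0.270), and at 7.85 ± 5.80 CPM in CFP and 14.7 ± 9.68 CPM in LMNB1 libraries (0.90 ± 0.64, adjusted p = 0.630). The exact permutation test with age gave p = 0.0571 for Lmnb2 and p = 0.0286 for Lmna (0.129 adjusted for both), and that between the viruses gave p = 0.2 and p = 0.286. Lmna was thus lower in all 4 old than in all 4 young libraries.

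**Figure D1:**
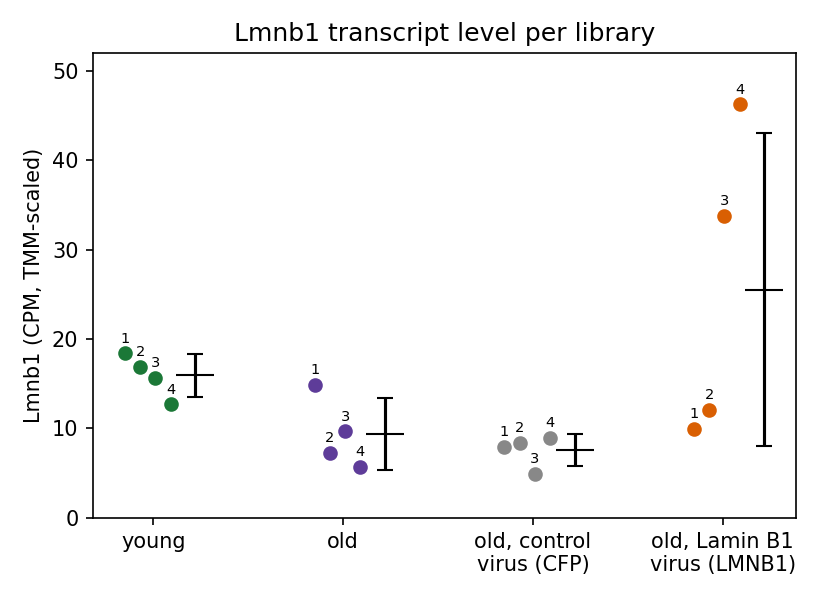
Lmnb1 level in TMM-scaled CPM (vertical axis) in each of the 16 libraries, by group; points are libraries with their replicate number, horizontal lines are group means and bars are 1 SD (n = 4). LMNB1 replicates 3 and 4 sit at 33.8 and 46.2 CPM, while LMNB1 replicates 1 and 2, at 9.95 and 12.1 CPM, lie just above the highest CFP library at 8.96 CPM.

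Among the genes called between young and old NSCs with a mean log2 CPM of at least 3 and no overlap between the groups, those with the largest increases included S100b, a calcium-binding protein of astrocytes, Spp1, the secreted phosphoprotein osteopontin, and Fth1, the heavy chain of the iron store ferritin. Fth1 was at 317 ± 73.0 CPM in young and 2576 ± 620 CPM in old libraries, a log2 fold change of 3.02 ± 0.42 (SE; adjusted p = 0.000166). Spp1 changed by 3.43 ± 0.67 (13.4 ± 10.7 to 144 ± 62.4 CPM, adjusted p = 0.00159) and S100b by 3.56 ± 0.82 (4.07 ± 4.21 to 48.0 ± 14.7 CPM, adjusted p = 0.00602). The deepest decreases among the genes that met these conditions were those of Cd93, a C-type lectin-like receptor, and Pdpn, the mucin-type membrane protein podoplanin. Cd93 was at 3550 ± 1043 CPM in young and 78.9 ± 67.8 CPM in old libraries (-5.49 ± 0.75, adjusted p = 0.000137), and Pdpn at 552 ± 84.0 and 25.6 ± 10.6 CPM (-4.43 ± 0.46, adjusted p = 2.07e-05). Cdkn1b, which encodes the cyclin-dependent kinase inhibitor p27, fell from 431 ± 121 to 36.2 ± 15.4 CPM (-3.57 ± 0.51, adjusted p = 0.00017).

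The other genes with large increases were B9d1, a protein of the ciliary transition zone, Rab26, a small GTPase, Qpct, glutaminyl cyclase, Psme1, a subunit of the proteasome activator PA28, and Fbln2, the matrix protein fibulin-2. Their log2 fold changes were 2.95 ± 0.56, 2.78 ± 0.32, 2.72 ± 0.42, 2.72 ± 0.41 and 2.55 ± 0.63, in that order. The other genes with deep decreases were Cybrd1, a ferric reductase (-4.06 ± 1.12), Prune2 (-3.97 ± 0.93), Lrp4, a receptor of the LDL receptor family (-3.78 ± 0.52), Hspa2, a chaperone of the HSP70 family (-3.75 ± 0.62), and Cit, citron kinase (-3.68 ± 0.53). In all, 1416 of 12710 genes tested passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 738 higher and 678 lower in old NSCs. Of these, 1283 had no overlap between the 4 young and the 4 old libraries. Among all genes tested, 16.7% had no overlap, against 2.86% expected by chance, a mean over splits whose spread was not computed. The count was 885 without old replicate 4, which ended the call of Cybrd1, as did leaving out young replicate 4 or old replicate 2. With no filter the calls of Cybrd1 (adjusted p = 0.0915) and Prune2 (adjusted p = 0.0542) ended. The count was 2 with the number of genes detected as a covariate. That number ran from 11617 to 12481 in young and from 12887 to 13770 in old libraries, without overlap. It stands in part for age itself, and the fit cannot tell age from a difference in genes detected. Young libraries also agreed less with each other (median Spearman's rho 0.874) than old ones did (0.928).

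The lists of ribosomal protein and respiratory chain genes were called higher in old NSCs. Of 83 cytosolic ribosomal protein genes, 72 rose and 2 fell over all genes tested (78 and 2 when adjusted over the list alone), with a median log2 fold change of 1.34. Rpl32 changed by 2.32 ± 0.38 and Rps20 by 2.03 ± 0.33, and Rpl5 (-0.83 ± 0.22) and Rps25 (-1.14 ± 0.26) were the 2 that fell; the call of Rpl5 ended without young replicate 3, old replicate 2 or old replicate 4. The list was called by camera with an adjusted p of 4.5e-41, and adjusted p = 0.193 with an estimated correlation. With offsets for transcript length it was still called and the median was 0.71, and with offsets for length and GC content it was 0.78. The list of nuclear genes of the respiratory chain was drawn by gene name and includes assembly factors such as Ndufaf4. Of its 89 genes, 46 rose and 0 fell over all genes tested (74 and 0 adjusted over the list alone), among them the cytochrome c oxidase subunit Cox6a1 (2.06 ± 0.36) and the ATP synthase subunit Atp5c1 (1.51 ± 0.29). Their median was 0.88, with an adjusted p of 2.7e-22 in camera and adjusted p = 0.247 with an estimated correlation. The median was 0.31 with offsets for transcript length and 0.35 with offsets for length and GC content, and the list was called with both. Of 12 mitochondrially encoded genes 3 rose and 0 fell over all genes tested (4 and 0 adjusted over the list alone; camera adjusted p = 0.0137, and adjusted p = 0.514 with an estimated correlation). They included mt-Nd1 (1.34 ± 0.36) and mt-Nd3 (1.88 ± 0.50), whose calls ended without old replicate 4 (adjusted p = 0.0644 and 0.0545) and with offsets for transcript length (adjusted p = 0.149 and 0.379), and that of mt-Nd3 also with limma voom and quality weights (adjusted p = 0.109). The mitochondrially encoded list was not called with offsets for transcript length (adjusted p = 0.879), and with offsets for length and GC content its test turned direction (adjusted p = 0.687). Counts of ribosomal protein genes made up 2.13 ± 0.228% of a young library and 4.87 ± 0.212% of an old one. In the same libraries the mean transcript length, weighted by counts, was 3720 ± 111 nt in young and 3013 ± 184 nt in old.

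Of 37 proteasome genes, 12 rose, among them Psmb5 (1.40 ± 0.22) and Psmb7 (1.65 ± 0.32), and 1 fell, Psma7 (-1.14 ± 0.29), over all genes tested, against 16 and 1 adjusted over the list alone. The list's adjusted p was 0.00136 in camera, and adjusted p = 0.514 with an estimated correlation. Its median log2 fold change was 0.48, and its call ended with offsets for transcript length (median 0.26, adjusted p = 0.39) and for length and GC content (0.27, adjusted p = 0.369). Of 11 genes of antigen presentation 1 rose over all genes tested, the peptide transporter Tap1 (0.349 ± 0.415 to 6.37 ± 6.24 CPM, adjusted p = 0.0442), and 0 passed when adjusted over the list alone. The list was called higher in old NSCs, with an adjusted p of 0.0170 in camera and adjusted p = 0.238 with an estimated correlation, and was not called with only the 8 libraries compared (adjusted p = 0.0567). The call of Tap1 ended in 7 of the 8 fits that left out 1 library and held only without young replicate 1. It also ended with limma voom and quality weights (adjusted p = 0.0922), with only the 8 libraries compared (0.145) and after thinning to the smallest library (0.0634).

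The lists of chromatin silencing and of the nuclear lamina and envelope were called lower in old NSCs, though most members did not pass. Of 22 genes of chromatin silencing, 0 rose and 5 fell over all genes tested (2 and 6 adjusted over the list alone). They included Cbx1 (-1.92 ± 0.27), Cbx3 (-1.87 ± 0.29) and Cbx5 (-1.09 ± 0.20), which encode the heterochromatin protein 1 family, and the DNA methyltransferase Dnmt3a (-1.53 ± 0.28). The call of Cbx5 ended with offsets for transcript length (adjusted p = 0.0995). The list's adjusted p was 0.00267 in camera, and adjusted p = 0.0922 with an estimated correlation. Of 20 genes of the nuclear lamina and envelope, 0 rose and 4 fell over all genes tested (0 and 5 adjusted over the list alone), with an adjusted p of 0.00476 in camera and adjusted p = 0.212 with an estimated correlation. The 4 were Banf1, the barrier-to-autointegration factor that binds DNA at the envelope (1740 ± 250 to 326 ± 127 CPM, -2.42 ± 0.34), the lamin B receptor Lbr (-2.02 ± 0.52), and the nuclear pore proteins Nup155 (-2.11 ± 0.32) and Nup93 (-1.01 ± 0.28). Leaving out old replicate 4 ended the calls of Lbr (adjusted p = 0.0564) and Nup93, and the call of Nup93 also ended without young replicate 2 or old replicate 2.

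The lists of NSC and radial glia genes, of Notch and Wnt signalling and of BMP, Id and quiescence genes were called lower in old NSCs. Most members did not pass and single ones rose. Of 20 NSC and radial glia genes, 1 rose and 5 fell over all genes tested (2 and 6 adjusted over the list alone), among them Notch2 (634 ± 165 to 97.3 ± 24.9 CPM, -2.70 ± 0.30), the glutamate transporter Slc1a3 (-1.45 ± 0.23) and the transcription factor Sox9 (-1.81 ± 0.33). The gene that rose was Thrsp (1.40 ± 0.29), a regulator of lipogenesis. Of 20 genes of Notch and Wnt signalling, 0 rose and 3 fell in both adjustments, over all genes tested and adjusted over the list alone. These were Notch2, its ligand gene Jag1 (-2.17 ± 0.39) and Tcf7l2, a transcription factor of the Wnt pathway (-2.68 ± 0.53). Of 13 genes of BMP signalling, Id proteins and quiescence, Nfib (-1.81 ± 0.23), Foxo3 (-1.79 ± 0.25) and Nfia (-2.41 ± 0.38) fell and the BMP target Id3 rose (1.13 ± 0.23), which was 1 up and 3 down over all genes tested and 1 and 4 adjusted over the list alone. The adjusted p of these 3 lists in camera was 0.00817, 0.00737 and 0.00817, in that order, and adjusted p = 0.0922, 0.164 and 0.0922 with an estimated correlation.

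Of 21 genes of cholesterol synthesis, 0 rose and 5 fell over all genes tested (3 and 7 adjusted over the list alone), among them Insig1, a regulator of sterol synthesis (1218 ± 220 to 263 ± 56.1 CPM, -2.21 ± 0.25). The adjusted p was 0.0150 in camera, and adjusted p = 0.164 with an estimated correlation. Of 20 DNA repair genes, 0 rose and 2 fell in both adjustments, over all genes tested and adjusted over the list alone, among them the recombination gene Rad54l (-1.05 ± 0.30). The list passed camera narrowly (adjusted p = 0.0435, and adjusted p = 0.239 with an estimated correlation), and its call ended without young replicate 1, young replicate 4, old replicate 1 or old replicate 2, with adjusted p between 0.0601 and 0.0913. It also ended with the stricter filter (adjusted p = 0.0644), with only the 8 libraries compared (0.142), and with offsets for transcript length (0.167), GC content (0.0557) or both (0.144). The call of Rad54l ended in 7 of the 8 fits that left out 1 library and held only without young replicate 2, and it ended with offsets for transcript length (adjusted p = 0.0759).

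Proliferation genes moved both ways. Of 25 genes of DNA replication and S phase, 2 rose and 4 fell in both adjustments, over all genes tested and adjusted over the list alone. Mcm2, a subunit of the replicative helicase (794 ± 149 to 96.5 ± 44.4 CPM, -3.04 ± 0.51), Uhrf1 (-1.99 ± 0.32) and the ribonucleotide reductase subunit Rrm2 (-1.10 ± 0.25) were among those that fell, and the dUTPase gene Dut was higher (1.10 ± 0.24). Of 25 genes of G2/M phase and mitosis, 2 rose and 3 fell over all genes tested (2 and 4 adjusted over the list alone), with a fall of the cyclin gene Ccnb2 (-1.60 ± 0.31) and of the mitotic kinase Plk1 (-1.36 ± 0.36) and a rise of Cks2 (1.85 ± 0.43). Neither list was called, with camera adjusted p of 0.0728 and 0.142. The list of S phase was called lower with limma voom and quality weights (adjusted p = 0.0376) and without young replicate 4 (0.00872), old replicate 1 (0.0224) or old replicate 4 (0.0372), and that of G2/M phase without young replicate 3 (0.00804). The call of Plk1 ended without old replicate 4 (adjusted p = 0.0675), and that of Cks2 with offsets for transcript length (adjusted p = 0.0591). Of 18 glycolysis genes 5 rose and 0 fell over all genes tested (7 and 3 adjusted over the list alone), among them Gapdh (1.03 ± 0.21) and Ldha (1.03 ± 0.24). That list did not pass camera either (adjusted p = 0.227), but fry called it higher (adjusted p = 0.0398).

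Markers of other cell types gave no list called by camera in the main fit between young and old. The alternative fry called the astrocyte list (adjusted p = 0.00856) and 3 mural and fibroblast genes (adjusted p = 0.0279) higher in old NSCs. Of these 3 genes 0 passed over all genes tested, and 1 rose adjusted over the list alone (camera adjusted p = 0.330). With the number of detected genes as a covariate, camera called the astrocyte list higher too (adjusted p = 0.0341). Among 13 astrocyte genes, many of which NSCs also express, Sparcl1 and S100b rose and Aldh1l1 (-1.82 ± 0.23) and Gja1 (-2.58 ± 0.33) fell over all genes tested, against 3 up and 2 down adjusted over the list alone (camera adjusted p = 0.432). Sparcl1, which encodes a secreted matrix protein, had the smallest adjusted p of all genes (3.74e-08). It was at 78.6 ± 25.6 CPM in old libraries and at 0.165 ± 0.329 CPM in young ones, where 3 libraries held 0 counts and young replicate 3 held 10, a log2 fold change of 8.98 ± 0.65. Whether young and old mice came from the same source is not given in the sources used here. Of 7 oligodendrocyte lineage and 3 microglia and macrophage genes tested 0 passed over all genes tested, and 0 passed adjusted over the list alone. These were counts of edgeR's quasi-likelihood test.

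Between old NSCs with the Lamin B1 virus and those with the control virus, no gene passed an adjusted p of 0.05. The 8 genes named next were picked by smallest p per direction among genes with a mean log2 CPM of at least 3. Predicted or unnamed genes were left out, so they need not include the smallest p of all genes tested. The genes with the smallest p and higher levels in LMNB1 libraries were Pam, which amidates peptide hormones (65.5 ± 14.8 CPM in CFP and 218 ± 119 CPM in LMNB1, log2 fold change 1.74 ± 0.33 SE, adjusted p = 0.0775), Akap12, a scaffold of protein kinase A (1.35 ± 0.26, adjusted p = 0.0887), Mdm2, the ubiquitin ligase of p53 (37.5 ± 13.7 and 146 ± 74.9 CPM, 1.96 ± 0.39, adjusted p = 0.0887), and Mib1, a ubiquitin ligase of Notch ligands (1.45 ± 0.29, adjusted p = 0.0887). Those with lower levels were Stmn1, the microtubule-destabilising protein stathmin (400 ± 50 and 183 ± 56.4 CPM, -1.13 ± 0.24, adjusted p = 0.116), the mitotic kinase Pbk (-0.99 ± 0.24, adjusted p = 0.165), the chromatin protein Hmgb1 (-0.93 ± 0.23, adjusted p = 0.167) and the ribonuclease H2 subunit Rnaseh2b (-1.01 ± 0.25, adjusted p = 0.167). For each of these 8 genes the 4 LMNB1 libraries did not overlap the 4 CFP libraries. All 8 passed with DESeq2 (adjusted p 0.000804 to 0.00556) and with limma voom and quality weights (0.00879 to 0.0277). None passed with limma voom without weights. Stmn1 had risen with age (1.37 ± 0.24, adjusted p = 0.000799).

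The count of 0 genes came from edgeR's quasi-likelihood test on all 16 libraries, where 1446 genes had an unadjusted p under 0.05 and the smallest adjusted p was 0.0674. DESeq2 called 122 genes (74 higher, 48 lower), limma voom 0, and limma voom with sample quality weights 43. Leaving out LMNB1 replicate 1 gave 149 calls, and leaving out LMNB1 replicate 2 gave 1. Groups of 4 did not overlap for 6.91% of genes, against 2.86% expected by chance. Genes move together, so the share of a single split can lie far from that value. Its spread over splits was not computed, and the excess cannot be judged. The median log2 fold change of all genes tested was 0.15 with TMM scaling and 0.41 with library size only, so the values of this comparison are to be read against that level.

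Ribosomal protein, respiratory chain and cell division genes lay lower in LMNB1 than in CFP libraries as groups. The first 2 lay below the CFP range only in LMNB1 replicates 3 and 4. Mean log2 CPM in LMNB1 replicates 1 to 4 was 9.18, 8.98, 7.97 and 7.55 for ribosomal protein genes (8.96 to 9.40 in CFP). For the respiratory chain it was 8.75, 8.533, 7.60 and 7.61 (8.525 to 8.84 in CFP). The G2/M list was lower in all 4 LMNB1 libraries (5.71 to 6.08) than in all 4 CFP libraries (6.28 to 6.61). Its mean was 6.04 in untransduced old and 6.43 in CFP libraries. All 83 ribosomal protein genes had negative log2 fold changes, with a median of -0.67, and examples were Rpl4 (-0.81 ± 0.23) and Rps2 (-0.76 ± 0.26). Without LMNB1 replicate 4 the median was -0.43. The nuclear respiratory chain list had 87 of 89 negative values and a median of -0.47, with the assembly factor Ndufaf4 at -0.70 ± 0.26 and Ndufb3 at -0.62 ± 0.25. That median was -0.71 without LMNB1 replicate 1 and -0.31 without LMNB1 replicate 3. The proteasome list had 34 of 37 negative values and a median of -0.39, with Psma5 at -0.85 ± 0.29 and Psmc2 at -0.66 ± 0.25. For the list of G2/M phase and mitosis, 24 of 25 values were negative and the median was -0.54, with the chromosomal passenger protein Birc5 at -0.84 ± 0.28 and the centromeric histone Cenpa at -0.75 ± 0.28. None of the members of these 4 lists passed over all genes tested, and 0 passed when adjusted over the list alone in edgeR's quasi-likelihood test. The camera adjusted p was 3.4e-40, 2.9e-23, 4.3e-11 and 1.4e-08 for the 4 lists in that order. None held with an estimated correlation, with adjusted p = 0.338, 0.391, 0.338 and 0.221. With offsets for transcript length the medians of the ribosomal, respiratory chain and proteasome lists were -0.32, -0.13 and -0.21, with offsets for length and GC content -0.35, -0.15 and -0.18, and all 3 were called in both.

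Targets of p53 lay higher in LMNB1 libraries. Of 19 tested, 15 had positive log2 fold changes and the median was 0.56, with Mdm2, the p53-induced genes Plk2 (0.98 ± 0.22) and Trp53inp1 (1.13 ± 0.48) and the BH3-only protein Pmaip1 (1.83 ± 0.80). Over all genes tested 0 passed in edgeR's quasi-likelihood test, and 2 were higher when adjusted over the list alone. Mdm2 and Plk2 passed over all genes with DESeq2 (adjusted p = 0.000804 and 0.00556). The list's adjusted p was 0.000902 in camera and 0.0256 in fry, which tests whether a list moves 1 way, and adjusted p = 0.22 with an estimated correlation. The list of DNA replication and S phase was lower (median -0.36, camera adjusted p = 0.00218, and adjusted p = 0.391 with an estimated correlation). In edgeR's quasi-likelihood test 0 members passed over all genes tested, and 1 was higher and 5 lower adjusted over the list alone. DESeq2 passed Dut (adjusted p = 0.0186), Tyms (0.0372) and Pcna (0.0392), and edgeR passed Mcm2 without LMNB1 replicate 1 (0.0353). Dut was at -0.89 ± 0.24, Tyms, thymidylate synthase, at -0.73 ± 0.22, and Pcna, the replication clamp, at -0.75 ± 0.23, while Mcm2 was at 1.74 ± 0.48 in the other direction, with 59.8, 60.7, 142 and 500 CPM in LMNB1 replicates 1 to 4 and 57.1 ± 5.52 CPM in CFP libraries. The lists of fatty acid oxidation (median -0.33, adjusted p = 0.0157; Eci1 at -0.67 ± 0.26) and of mitochondrially encoded genes (median -0.41, adjusted p = 0.0307; mt-Co1 at -0.57 ± 0.33) were called lower, with adjusted p = 0.459 and 0.613 with an estimated correlation, and 0 members passed over all genes tested or adjusted over the list alone. The call of fatty acid oxidation ended without LMNB1 replicate 3 (median -0.20, adjusted p = 0.0609), with offsets for transcript length (-0.20, adjusted p = 0.123) and with offsets for length and GC content (-0.17, adjusted p = 0.102). That of the mitochondrially encoded list ended without CFP replicate 1 or 2 or without LMNB1 replicate 3 or 4 (lowest adjusted p 0.0571, highest 0.655). It ended too with limma voom and quality weights (adjusted p = 0.29), with only the 8 libraries compared (0.0621) and with offsets for transcript length (0.946). Its median was -0.21 without LMNB1 replicate 3 and -0.15 without LMNB1 replicate 4, it was -0.68 without LMNB1 replicate 1, and its test turned direction with offsets for transcript length and GC content (adjusted p = 0.670). The nuclear lamina and envelope list was not called, with 17 of 20 positive values, a median of 0.42 and a camera adjusted p of 0.0551. This list includes Lmnb1, the gene added by the virus, and was not tested without it. It was called higher with library size only (adjusted p = 0.0356) and without CFP replicate 2 (0.0195), LMNB1 replicate 1 (0.0376) or LMNB1 replicate 2 (0.0353). Not called either was the list of immediate early and dissociation genes, which includes markers of cell handling, with 12 of 17 positive values, a median of 0.56 and an adjusted p of 0.0717. It was called higher with offsets for transcript length (adjusted p = 0.0151), without CFP replicate 1 (0.0171) and without LMNB1 replicate 2 (0.0362).

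The LMNB1 libraries spread more than those of the other virus. Ribosomal protein genes made up 5.56, 5.47, 3.48 and 2.41% of counts in LMNB1 replicates 1 to 4 and 5.94 ± 0.553% in CFP libraries. Mitochondrially encoded genes made up 16.0, 14.8, 11 and 7.77% in LMNB1 replicates 1 to 4 and 14.4 ± 0.713% in CFP libraries. The count-weighted transcript length was 2729, 2967, 3371 and 3338 nt in LMNB1 replicates 1 to 4 and 2749 ± 66.9 nt in CFP libraries. No list of markers of another cell type was called, with camera adjusted p of 0.164 for astrocyte and 0.557 for oligodendrocyte lineage genes. The mean log2 CPM of the astrocyte list was nevertheless higher in all 4 LMNB1 libraries (4.63 to 4.83) than in all 4 CFP libraries (4.15 to 4.39), with 9 of 13 positive values and 0 members past the threshold over all genes tested or adjusted over the list alone.

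**Figure D2:**
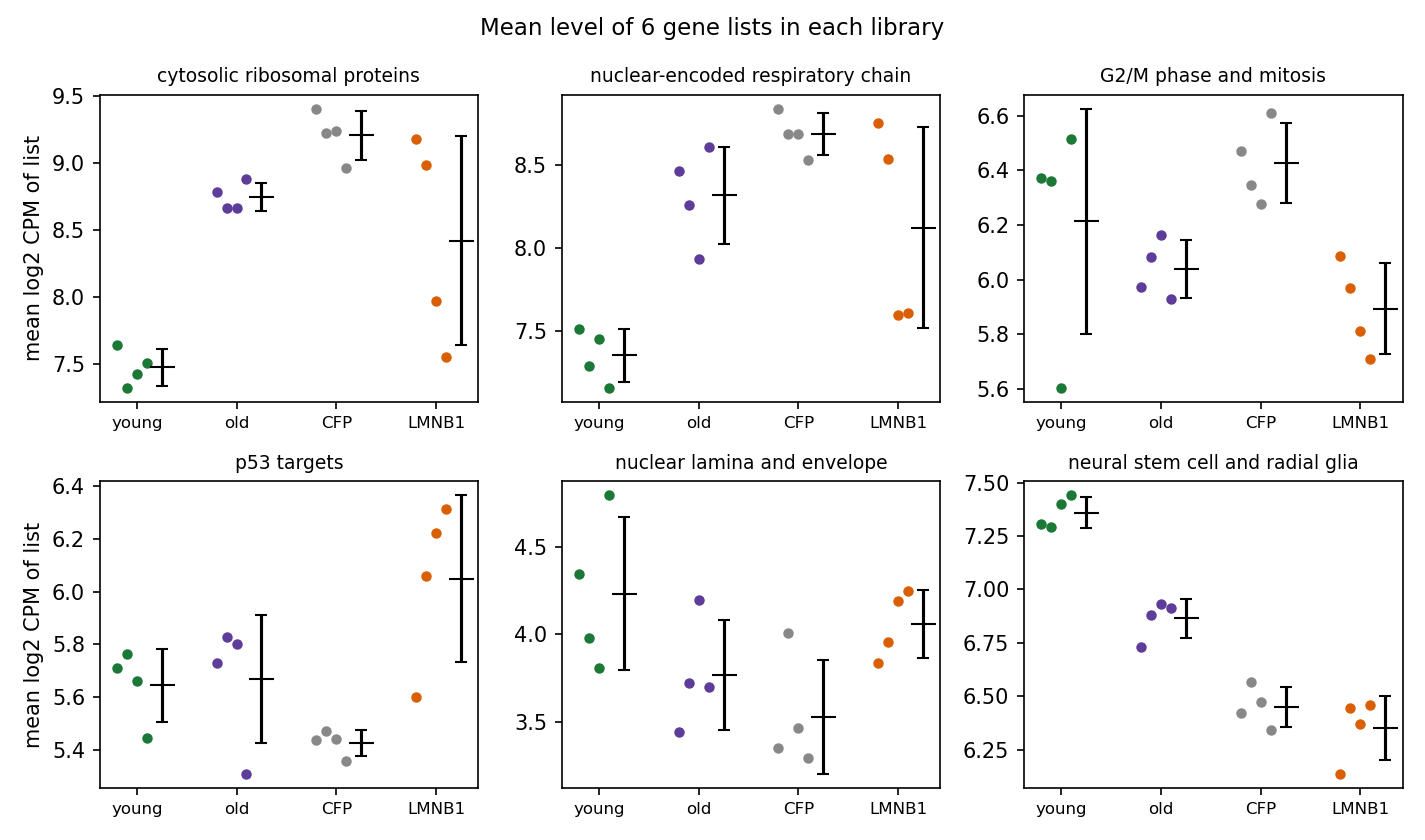
Mean log2 CPM (vertical axis) of the members of 6 gene lists in each of the 16 libraries, by group; points are libraries, horizontal lines are group means and bars are 1 SD (n = 4), and the vertical axes differ between panels and do not start at 0. For ribosomal protein genes, whose share of counts was 2.13 ± 0.228% in young and 4.87 ± 0.212% in old libraries, LMNB1 replicates 1 and 2 lie near the CFP libraries and LMNB1 replicates 3 and 4 lie lower.

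The genes that changed with age tended to lie on the opposite side with the Lamin B1 virus. Of the 738 genes higher in old NSCs, 641 (86.9%) had a negative LMNB1 over CFP fold change, with a median of -0.48. Of the 678 genes lower in old NSCs, 585 (86.3%) had a positive one, with a median of 0.60. As lists they were called in camera with adjusted p of 8.3e-38 and 7.6e-20, while adjusted p = 0.287 and 0.407 with an estimated correlation and 0.126 and 0.179 in fry. The median of the genes higher in old NSCs was -0.30 with library size only and -0.24 with the number of genes detected as a covariate. That of the genes lower in old NSCs was 0.20 without LMNB1 replicate 4, 0.33 with limma voom and quality weights and 0.34 with the covariate. Across all 12710 genes, which are not independent replicates, the age and LMNB1 fold changes gave Pearson's r = -0.13 and Spearman's rho = -0.29, and no library entered both comparisons. On differences of mean log2 CPM the values were r = -0.18 and rho = -0.25. An exact two-sided permutation of the LMNB1 and CFP libraries over 70 assignments gave p = 0.314 and p = 0.343, so the opposite direction was not larger than other assignments of these 8 libraries gave. The smallest p these permutations can give is 0.0286. With each of the 16 libraries left out in turn, r of the fitted fold changes ran from -0.16 to -0.05, the latter without LMNB1 replicate 4. For the genes with a mean log2 CPM of at least 3 r was -0.50 and for the genes called with age it was -0.42, each with an exact permutation p of 0.343. With offsets for length and GC content it was -0.09 (permutation p = 0.686).

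**Figure D3:**
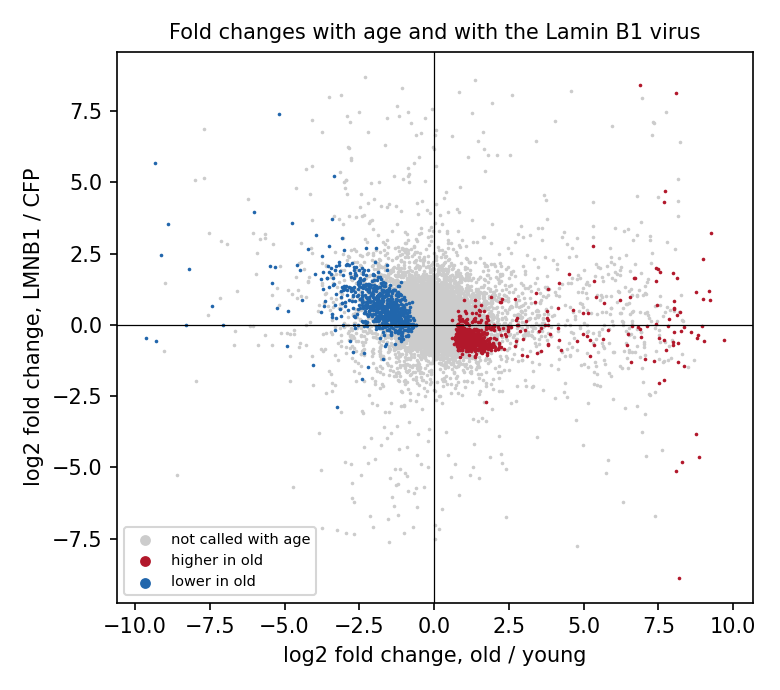
Log2 fold change of LMNB1 over CFP (vertical axis) against log2 fold change of old over young (horizontal axis) for the 12710 genes tested; each point is a gene, red and blue mark the 738 genes higher and the 678 genes lower in old NSCs at an adjusted p of 0.05, and grey the others. The red points lie mostly below the horizontal line (641 of 738) and the blue ones mostly above it (585 of 678). The exact permutation p over libraries was 0.314, for Pearson's r of differences of mean log2 CPM rather than of the fold changes shown.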

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

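The tests of the Lmnb1 level in the CFP and young libraries were chosen only after the result was seen, and the fit with length and GC offsets and the matched random lists were chosen after the data had been seen but before their own results were.

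In groups of 4 libraries, the gap of the highest or lowest library to its nearest neighbour, divided by the range, was compared with Dixon's 95% critical value for 4 libraries, which chance passes in about 1 of 20 groups. For genes the gap was taken on log2 CPM, while the values below are CPM. Of 277 groups tested, 17 passed it, which is close to the rate of chance, so single flags carry little weight. Young replicate 1 stood apart in genes detected (12481 against 11617 to 11721), Prune2 (34.4 against 169 to 229 CPM), mt-Nd1 (13080 against 10650 to 10870 CPM), Cbx3 (306 against 378 to 395 CPM) and Banf1 (1371 against 1821 to 1927 CPM). Young replicate 2 stood apart in Fbln2 (0.735 against 18.6 to 35.0 CPM) and Timp1 (1.94 against at most 0.0555 CPM). Young replicate 3 stood apart in Gapdh (279 against 322 to 332 CPM) and Sparcl1 (0.659 CPM against 0). Old replicate 3 stood apart in Spp1 (53 against 158 to 193 CPM), Insig1 (179 against 287 to 296 CPM), Aldh1l1 (82.9 against 54.4 to 57.4 CPM) and Apoe (90.6 against 163 to 180 CPM), and old replicate 2 in Ccl2 (1.76 against 11.4 CPM or more). CFP replicate 1 stood apart in Rpl4 (2355 against 2176 to 2203 CPM) and Pcna (431 against 544 to 561 CPM), and CFP replicate 4 in Fos (11.8 against 31.1 to 36.6 CPM).

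The first pattern weighed is the higher level of ribosomal protein genes in old than in young NSCs and the lower level in LMNB1 than in CFP libraries, with shorter counted transcripts where the list was higher. Transcript length and GC content as the whole cause were tested against 10000 random lists matched on length, GC content and expression. With age the list's median of 1.34 lay at percentile 100 of the matched lists, whose central 95% ran from 0.55 to 0.80. With the Lamin B1 virus the median of -0.67 lay at percentile 0, where the matched lists ran from -0.47 to -0.33. The list thus moved further than genes of like length and GC content. The matched genes were drawn independently, without respiratory chain, proteasome and mitochondrially encoded genes, and had a lower mean log2 CPM (7.90 against 8.46). Ribosomal protein genes move together (estimated correlation 0.80 with age and 0.78 with the virus). The matched range is therefore too narrow to exclude length and GC content as the whole cause. The matched lists moved the same way and may account for part of the shift. Reads shared with pseudogene copies and a difference in RNA yield were not tested.

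The second pattern is the opposite direction of age and LMNB1 fold changes, with a Spearman's rho of -0.29 across genes. After thinning to 1 depth rho was -0.31 (-0.3083), which argues against library depth. With length and GC offsets rho was -0.2089 and without LMNB1 replicate 4 it was -0.1556, against a bound of -0.2 and an SD of 0.0389 over the fits that left out 1 library, a margin added after the values were seen. Trends in length and GC content and the weight of LMNB1 replicate 4 therefore cannot be told apart from an effect of the virus at this number of libraries. That added Lamin B1 moves age-related transcripts back may be an explanation, but it stays a hypothesis. The exact permutation p over libraries was 0.343 for rho on differences of mean log2 CPM. The mean log2 CPM of ribosomal protein genes was 7.47 in young, 8.75 in old, 9.21 in CFP and 8.42 in LMNB1 libraries. It was 7.15, 7.65, 8.05 and 7.59 for proteasome genes and 4.23, 3.77, 3.53 and 4.06 for the nuclear lamina list, which includes Lmnb1, in the same order. In these lists the CFP mean lay further from young than the old mean did, which can add to the opposite direction. LMNB1 was not tested against untransduced old libraries.

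The third pattern is the spread of Lmnb1 within the LMNB1 group, from 9.95 CPM in replicate 1 to 46.2 CPM in replicate 4. A swap of labels of LMNB1 replicates 1 or 2 with CFP libraries would leave libraries with the Lamin B1 virus under a CFP label. The highest CFP library held 8.963 CPM, which argues against a swap with a library at the level of LMNB1 replicates 3 and 4. A swap with a library of low Lmnb1 level is not excluded by this value. A shift of LMNB1 replicates 3 and 4 towards the young libraries would end at the young level, and the highest young library held 18.4 CPM (15.9 ± 2.42 over the 4), while these 2 held 33.8 and 46.2 CPM. Both lay above the highest young library by more than 3 SD of the young libraries, a bound set after the values were seen, which argues against such a shift as the whole cause. A wrong label with no partner among the CFP libraries stays open, and a different virus load per library may be another source, which was not tested.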

How the results depend on the processing

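The offsets for transcript length and GC content, and the correlation without 4 lists, were chosen only after the data were seen; the other alternatives were planned. For old against young, 2 genes were called with the number of detected genes as a covariate, and 885 to 1489 with 1 library left out, the lowest without old replicate 4. For LMNB1 against CFP, the count of 0 in edgeR became 122 with DESeq2, 43 with limma voom and quality weights, 6 with no filter, 3 with the GC offset, 1 with the 8 compared libraries alone and 1 after thinning. Leaving out 1 library gave 0 to 149, the highest without LMNB1 replicate 1. For CFP against old, 53 became 154 with DESeq2, 33 with voom, 321 with voom and quality weights, 149 with the 8 libraries alone and 23 with the covariate. It was 15 to 43 with 1 library left out, and only leaving out old replicate 1 kept it within 1.5 times. With an estimated correlation 0 lists were called for either comparison, while fry called 17 with age (10 higher, 7 lower), against 12 in camera, and 1 for LMNB1 against 8. The age-called genes as lists lost their calls in both, where the medians of -0.4837 and 0.596 are fixed since the fold changes are the same, with adjusted p = 0.287 and 0.407 with an estimated correlation and 0.126 and 0.179 in fry. The mitochondrially encoded list turned its test direction with length and GC offsets, with medians of 0.1888 (age) and 0.0653 (LMNB1). Fewer samples are the construction of the fits without a library; for the other settings the cause was not tested. Lmnb1 stayed on its side of the threshold in each fit, from -1.075 to -0.583 with age and from 1.304 to 2.027 with the virus when 1 library was left out; DESeq2 gave no adjusted p for the latter. Of 66 genes tested this way by name with age, 53 kept their side of the threshold in every setting other than the covariate, and none reversed. Of the 27 named for LMNB1 against CFP none reversed either, 13 of the 24 with an adjusted p in DESeq2 passed there and 10 passed with voom and quality weights, and 4 of the 12 of CFP against old kept their call in every setting. Of the 12 lists called with age, all lost the call with an estimated correlation, 8 kept it with the covariate and 9 with length and GC offsets.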

Other observations

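The tests of other splits of the libraries were planned before their results were seen, and the genes Egr1, Fosb, Cspg4 and Slc1a2 were chosen after their values were seen.

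Old NSCs with the control virus had lower levels of immediate early and dissociation genes than untransduced old NSCs, a list that also marks the handling of cells. The immediate early transcription factor gene Fos was at 271 ± 31.9 CPM in old and 28.5 ± 11.3 CPM in CFP libraries (log2 fold change -3.25 ± 0.34, adjusted p = 4.9e-05, n = 4 each, edgeR's quasi-likelihood test). Egr1 was at 307 ± 155 and 96.1 ± 11.3 CPM (adjusted p = 0.024), Zfp36, an RNA-binding protein, at 22.4 ± 6.58 and 3.11 ± 0.936 CPM (adjusted p = 0.0448), and Fosb at 16.5 ± 7.41 CPM in old libraries and 0 counts in all 4 CFP libraries (adjusted p = 0.00368). These were the 4 of 17 immediate early and dissociation genes that fell over all genes tested, and 9 fell when adjusted over the list alone. This list was called in camera (adjusted p = 1.1e-15) and was called with an estimated correlation too (adjusted p = 0.000896). The Notch target Hes5 (-3.38 ± 0.59) and the lipid carrier Apoe (-3.19 ± 0.62) were also lower in CFP libraries. The chemokine Ccl2 (2.86 ± 0.59), Ecrg4 (2.56 ± 0.45), the small heat shock protein Cryab (130 ± 23.6 to 591 ± 73.8 CPM, 2.19 ± 0.29) and the growth factor Hbegf (1.85 ± 0.32) were higher. The calls of Ccl2 and Zfp36 ended in each of the 8 fits that left out 1 library, with adjusted p up to 0.132 and 0.226, and those of Egr1, Cspg4, Apoe and Hes5 in some of them. With offsets for transcript length the calls of Ccl2 (adjusted p = 0.0548), Ecrg4 (0.0574) and Cspg4 (0.117) ended. The number of detected genes as a covariate ended those of Ccl2 (adjusted p = 0.074), Zfp36 (0.124), Egr1 (0.156) and Cspg4 (0.101). With limma voom those of Hes5 (0.0719), Zfp36 (0.15), Egr1 (0.0584), Cspg4 (0.123) and Slc1a2 (0.0662) ended, with no filter that of Apoe (0.104), and with DESeq2 size factors that of Zfp36 (0.0520).

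In the same comparison, 1 of 7 oligodendrocyte lineage genes fell, Cspg4 (42.3 ± 14.3 to 7.91 ± 3.30 CPM), and 2 when adjusted over the list alone; the list's adjusted p was 7.1e-05, and adjusted p = 0.0573 with an estimated correlation. Of 13 astrocyte genes 2 fell in both adjustments, over all genes tested and adjusted over the list alone, Apoe and the glutamate transporter Slc1a2 (53.8 ± 20.7 to 10.1 ± 5.46 CPM). That list's adjusted p was 0.0419, and adjusted p = 0.165 with an estimated correlation. The 25 genes of G2/M phase and mitosis were higher in CFP libraries as a list (22 positive values, adjusted p = 5.5e-06, and adjusted p = 0.234 with an estimated correlation), with 0 members past the threshold. So were those of ribosomal proteins (81 of 83 positive, adjusted p = 6.4e-19, and adjusted p = 0.341 with an estimated correlation), the nuclear respiratory chain (85 of 89, 3.2e-13 and 0.383), the proteasome (34 of 37, 6.6e-10 and 0.256) and S phase (15 of 25, 0.0142 and 0.341), also with 0 members past the threshold over all genes tested or adjusted over the list alone. The call of the respiratory chain ended with offsets for transcript length (adjusted p = 0.0653), and that of S phase without old replicate 3 (0.0744) or CFP replicate 2 (0.0869). Of 20 NSC and radial glia genes Hes5 fell (2 up and 7 down adjusted over the list alone), and the list was called lower (adjusted p = 0.0321, and adjusted p = 0.144 with an estimated correlation). That call ended without young replicate 1 or 3, old replicate 2 or 4 or any 1 of the 4 CFP libraries, with adjusted p up to 0.101. The call of the astrocyte list ended without young replicate 3 (0.0548), old replicate 1 (0.0945), old replicate 4 (0.117) or CFP replicate 2 (0.0869), with the stricter filter (0.0703) and with limma voom and quality weights (0.0868). In all 53 genes were called, 11 higher and 42 lower in CFP libraries, and the median log2 fold change of all genes was -0.11 with TMM scaling and -0.30 with library size only. DESeq2 called 154 genes, and edgeR 15 to 43 when 1 library was left out, with counts more than 1.5 times lower for each library but old replicate 1. The virus, the reporter sort and the handling of transduced cells differ together between these groups, and this comparison does not separate them.

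Further lists between young and old gave no call in camera. Of 13 genes of senescence-associated secretion, Spp1 and Timp1 (0.5 ± 0.963 to 9.02 ± 4.45 CPM) were higher, and 2 rose and 1 fell in both adjustments, over all genes tested and adjusted over the list alone (adjusted p = 0.0579 in camera), and fry called the list higher (adjusted p = 0.000606). Camera called it without young replicate 1 (0.0491) or 2 (0.0298), old replicate 2 (0.0339) or 4 (0.0372), or CFP replicate 3 (0.0497). The call of Timp1 ended without old replicate 4 (adjusted p = 0.0520), with offsets for transcript length (0.0604) and with only the 8 libraries compared (0.134), and its fold was larger without young replicate 2. Of 14 genes of neuronal differentiation, Sox11 fell (2345 ± 684 to 619 ± 169 CPM, -1.92 ± 0.29) and 2 rose, among them Stmn1 (adjusted p of the list 0.930). Of 17 immediate early genes Fos rose with age (109 ± 19.4 to 271 ± 31.9 CPM, 1.32 ± 0.32), with 1 up and 0 down in both adjustments and an adjusted p of the list of 0.922. Of 9 interferon response genes 0 passed (adjusted p = 0.142 in camera), and fry called that list higher (adjusted p = 0.00550).

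Each count was set against all 35 splits of the 8 libraries compared. For old against young, 1 of 35 splits, the real one, gave 1416 genes, and the highest of the others gave 1. That argues against chance for the number of genes but does not exclude it, since 1 of 35 is the lowest share these splits can give. The other splits mix young and old libraries, so a group difference of any source adds to their spread and lowers their counts. The 12 lists called with age were also reached by 1 of 35 splits only, with 11 as the highest of the others. For CFP against old, 1 of 35 splits gave 53 genes, and the highest other gave 0. For LMNB1 against CFP, 4 of 35 splits gave at least the 8 lists called, with 9 as the highest other, so chance is not excluded for the number of lists. With 0 genes called, all 35 of 35 splits necessarily gave at least as many, so that count says nothing about chance (highest other 1).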
